A study of Mus musculus with 12 samples.

How the data were processed

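Gene expression was measured by RNA sequencing in 12 libraries of E14 mouse embryonic stem cells (129/Ola strain). Per the labels, cells were transfected with a construct carrying a single guide RNA (sgRNA, the RNA that directs Cas9 to its site) and selected with puromycin, and stranded mRNA libraries were made from total RNA. Each of 10 libraries carried guides against a different regulatory element: 9 were labelled by a CRE number and 1 was labelled Oct4 DE, here Oct4_DE. The other 2 libraries, NT1 and NT2, had guides labelled NT and the condition WT. Each target was sequenced once. No label says whether NT1 and NT2 came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

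The deposited table holds FPKM (sequenced fragments scaled to transcript length and to library size) for 24823 gene symbols. Per the submitters' processing notes, the tools were STAR, Cuffdiff and Cuffnorm and the genome build was mm9; versions, settings and the gene annotation are not given in the sources used here. Cuffnorm scales libraries to each other, so the values were taken as deposited. 4353 genes were at 0 in every library. All 12 value columns were matched to samples by their labels.

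FPKM carry no read counts, and the total depth is unknown. Values of genes under 0.3 FPKM move in steps of 1 read, and the ratio of such steps between libraries gave the reads of each library relative to NT1. They ranged from 0.44 (CRE135 and CRE18) to 1.13 (NT2). Between 9.8% and 18.1% of low genes stood at the common step ratio, so these are rough estimates. FPKM divided by length also makes very short genes unstable: a snoRNA or microRNA gene can be listed at 0 in most libraries and at a high FPKM in 1.

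Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. Values were analysed as log2(FPKM + 1), so a difference understates the change of low genes. Genes with a mean of at least 1 FPKM over all libraries were tested (11642 genes). Genes set apart in a library were called with limma-trend, 1 library against the other 11, two-sided, at a Benjamini-Hochberg adjusted p under 0.05 within each library. The lone library is assumed to vary like the others. The same fit was run on NT1 and NT2 for comparison, with all 10 targets then in the reference. Because a target has no replicate, genes at least doubled or halved against both NT libraries (1 log2 unit) were counted without a test, with NT1 against NT2 as background. The 10 enhancer-targeted libraries were compared with the 2 NT libraries by limma-trend, and all 66 splits into 10 and 2 were counted. Gene lists (22 with at least 5 members tested) were tested with camera, limma's competitive set test, with a preset correlation of 0.01, adjusted over lists for the pooled comparison and over lists and the 12 libraries together (264 tests) for single libraries. Lists, tests, alternatives and the naming rule were fixed before the data were examined.

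The naming rule took Pou5f1, Sox2 and Nanog everywhere. Per target it took the 5 largest rises and 5 largest falls from the NT mean among called genes that moved the same way against both NT libraries (10 and 10 for Oct4_DE). For the pooled comparison it took the 10 largest rises and falls with an adjusted p under 0.05, and for each passing list up to 4 members with the smallest p. A target without called genes was to be described by its 2 largest rises and 2 largest falls, given as values. Genes named outside this rule are said to be chosen after their values were seen. A result that needs an item withheld for evaluation was left out. Where the rule named more list members than are useful to print, some are left out.

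Transcript length and GC content came from the longest transcript per symbol in a GENCODE annotation of a later mouse build, used only for lengths, biotypes and gene order. 11592 of the tested genes (99.6%) had a length. 128 tested genes were shorter than 300 nt, had a small-RNA name or had no length. Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, centring each library on its median, leaving out each NT library, leaving out each enhancer-targeted library in turn for the pooled comparison, robust moderation, the 2 NT libraries alone as reference, an estimated correlation in camera, and random lists matched on level. Alternatives added after seeing the data left out genes under 300 nt, removed a loess trend on log2 transcript length (and on GC content) from each library, and left out CRE210, Oct4_DE or CRE111.

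The fits were tested on simulated data with real gene means, 12 libraries and 200 changed genes in each of 5 runs on 11642 genes. Noise was drawn independently for each gene and library, and changes were not placed in the lowest genes. Differences shared between libraries, as in the real data, were absent, so the recovery rates do not give the power of the real fits. With the spread of all 12 libraries, 1 library against 11 recovered 71.8% of genes changed 2-fold and 99.0% changed 4-fold, with 8.2 unchanged genes called on average. With the spread of the libraries other than Oct4_DE, CRE111 and CRE210, the 2-fold figure was 95.8%. With a length trend added to the single library, 74.6 unchanged genes were called on average with the spread of all libraries and 546 with the narrower spread, against 10.2 and 13.8 once the trend was removed. For 10 libraries against 2 and the spread of all libraries, 89.4% of 2-fold and 99.4% of 4-fold changes were recovered.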

Results

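The data are FPKM of 12 libraries of mouse embryonic stem cells, a line that self-renews in culture and can form all tissues of the embryo. The series title places them in a CRISPR-Cas9 screen for enhancers that pluripotent cells need. 9 libraries carried guides against numbered CREs, 1 against the distal enhancer of Oct4 (the gene Pou5f1) and 2 carried NT guides. Library totals ran from 429997 FPKM in CRE135 to 565915 in CRE210, and genes above 0 from 17567 in CRE18 to 18513 in Oct4_DE. Relative to NT1, estimated reads were 1.12 in Oct4_DE and CRE210, 1.13 in NT2, 0.93 in CRE4 and 0.44 to 0.77 in the other 7 libraries. Over tested genes the Spearman correlation was 0.994 between NT1 and NT2 and at least 0.941 between any pair.

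Pou5f1, which encodes the pluripotency factor Oct4, was measured first because 1 library targets its distal enhancer. It stood at 833 ± 7.13 FPKM in NT (SD, n = 2) and at 629 FPKM in Oct4_DE, 75.4% of the NT mean. Oct4_DE was not the lowest: CRE32 stood at 621 FPKM, CRE4 at 648, CRE135 at 658, CRE18 at 659, CRE77 at 674, CRE132 at 685, CRE140 at 727 and CRE111 at 774. CRE210 was the only target above NT in the deposited values, at 958 FPKM. Against the other 11 libraries, Pou5f1 in Oct4_DE differed by -0.21 on the log2 scale (SE 0.20, limma adjusted p = 0.47), so the deposited values do not set this library apart by Pou5f1. With the length trend described next removed, an alternative chosen after seeing the data, the difference was -0.53 (SE 0.12, limma adjusted p = 0.027). The order of the targets also changed then: Oct4_DE was lowest, at 64.4% of NT, followed by CRE32 at 82.0%, while CRE210 was below NT, at 93.2%, and CRE111 above it, at 109.1%.

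Sox2 and Nanog encode 2 further core factors. Sox2 was at 207 ± 6.08 FPKM in NT (SD, n = 2), at 188 in Oct4_DE and at 260 in CRE111, its lowest and highest targets. Nanog was at 427 ± 7.98 FPKM in NT (SD, n = 2), at 394 in Oct4_DE and at 449 in CRE111. Neither gene passed the limma test in any library.

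**Figure D1:**
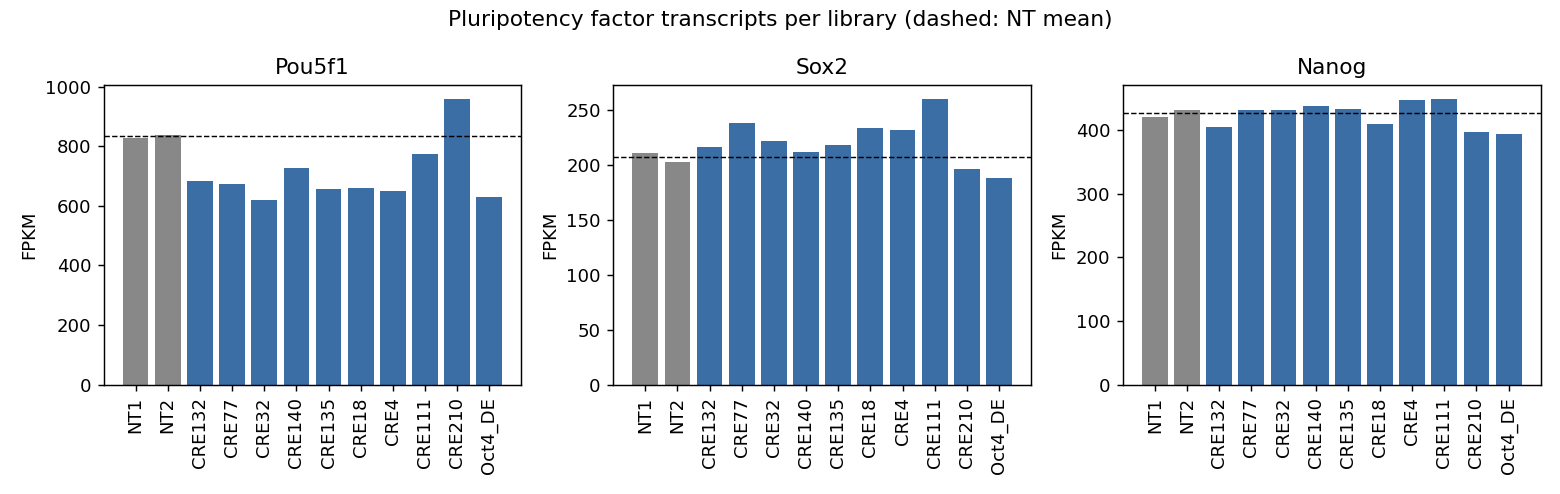
FPKM of Pou5f1, Sox2 and Nanog in each library, with the 2 NT libraries in grey and the mean of NT as a dashed line. Pou5f1 lies below the NT mean in every target except CRE210, at 958 FPKM.

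Short and long transcripts moved apart in every target library. In Oct4_DE and CRE210, transcripts under 1000 nt were higher than in NT (median log2 difference 0.33 and 0.39 over 354 genes) and transcripts of at least 8000 nt were lower (-0.41 and -0.53 over 220 genes). In the other 8 targets the order was opposite, from -0.16 and 0.12 in CRE140 to -0.36 and 0.36 in CRE4. Across 6323 genes, which are not independent replicates, the Spearman correlation of the difference with length was -0.58 in Oct4_DE, -0.69 in CRE210 and 0.41 to 0.66 elsewhere, against -0.001 between NT1 and NT2. This trend runs beside every comparison of a target with NT given here. The labels give no preparation or sequencing batch, so a batch behind the opposite trend of Oct4_DE and CRE210 cannot be told apart from their targets.

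**Figure D2:**
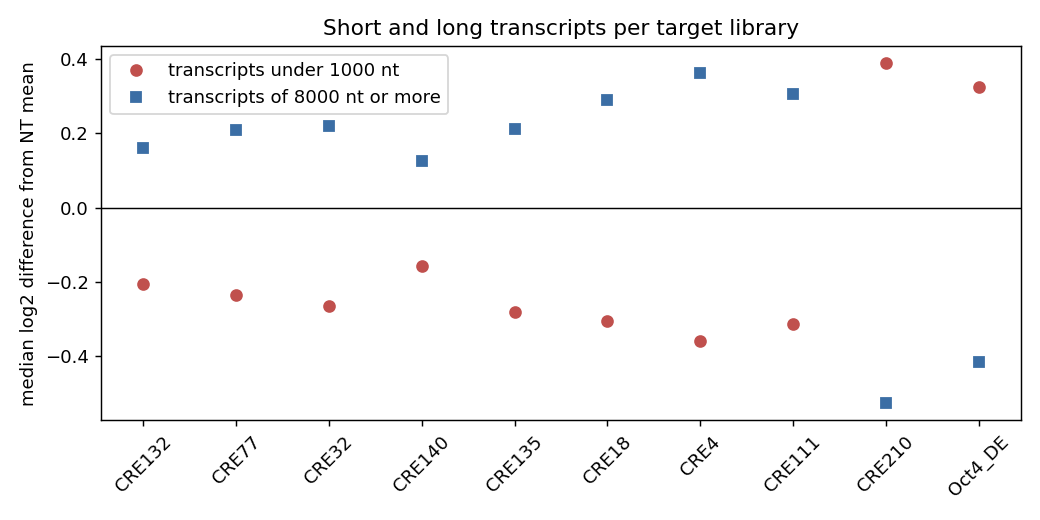
Median log2 difference from the NT mean per target library for transcripts under 1000 nt (circles) and of 8000 nt or more (squares). Oct4_DE and CRE210 have the short transcripts above 0 and the long ones below, and the other 8 targets have the reverse.

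In Oct4_DE, 267 single genes stood apart, among them 4 of 15 trophectoderm markers. Among genes of at least 300 nt, the largest rises were in Khdc3, an oocyte and early embryo gene, at 86.4 FPKM against 12.92 and 11.97 in the NT libraries, and in Trim43a, at 15.8 against 2.93 and 3.74. Ly6a (33.9 FPKM against 7.20 and 9.38), Tagln, an actin-binding smooth muscle protein (6.18 against 1.13 and 1.01), Calcoco2 (134 against 38.6 and 44.0) and Crxos (28.6 against 7.85 and 9.04) also rose. So did Alppl2 and Sfn, by 1.53 and 1.52 log2 units from the NT mean, Gm9112 (5.49 FPKM against 1.25 and 1.35) and the microRNA gene Mir496b, listed at 0 in both NT libraries and at 22.1 FPKM here. The largest falls were in Fstl1, a secreted glycoprotein (4.68 FPKM against 17.3 and 15.7), Mcf2 (3.45 against 9.72 and 8.71), Zfp266 (5.69 against 14.6 and 13.2) and the imprinted growth factor adaptor Grb10 (16.8 against 38.4 and 37.9). Skil, the guidance cue Ntn1, Napsa, Atp2a3, the Wnt antagonist Sfrp1 and Stx3 fell by 0.92 to 1.14 log2 units from the NT mean.

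Of 15 tested trophectoderm markers, 4 were higher in Oct4_DE and none lower (7 higher and 0 lower adjusted over the list alone), and 10 lay above the mean of the other libraries. Rhox9 (8.05 FPKM against 3.07 and 2.90), the imprinted RNA H19 (8.21 against 3.04 and 3.09), Rhox6 (8.58 against 3.14 and 3.79) and the keratin Krt8 (32.1 against 14.1 and 15.0) rose. The list passed camera, with a median of 0.38 log2 units above the other libraries (adjusted p = 0.00055), but not with an estimated correlation (adjusted p = 0.33). With the length trend removed the median was 0.19 (adjusted p = 0.00081). Other lists had medians of that size or higher then: 0.28 for Myc and ribosome biogenesis, 0.25 for primitive endoderm, 0.20 for cholesterol synthesis and 0.19 for heat shock. Against NT, the trophectoderm median was 0.40 in Oct4_DE, but it was also high in CRE210, at 0.21 and percentile 98.2 of random lists. With the length trend removed the medians against NT were 0.41 in Oct4_DE and 0.135 in CRE210, and the percentile of CRE210 was 94.08. Markers of the 2-cell-like state did not pass (adjusted p = 0.062, and adjusted p = 0.36 with the length trend removed). The list of Myc targets and ribosome biogenesis passed as well, with a median of 0.27 (adjusted p = 0.0013; adjusted p = 0.74 with an estimated correlation). None of its 20 members passed alone among all genes, and 3 were higher adjusted over the list alone. Bop1 stood at 155 FPKM against 110 and 113 in NT, Srm at 228 against 157 and 157, Fbl at 94.1 against 69.3 and 68.4, and Pa2g4 at 285 against 224 and 241.

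In all, 267 genes set Oct4_DE apart from the other 11 libraries by limma, 156 higher and 111 lower, and each moved the same way against both NT libraries. At least doubling or halving against both NT libraries counted 59 and 27 genes, against 24 genes between NT1 and NT2, of which 22 were under 300 nt or without a length. Of the 59 and 27 genes, 9 and 2 were of this kind. The rule is easier to meet between NT1 and NT2, where it rests on a single comparison. The limma count depended on which libraries formed the reference: it was 4030 without CRE210, which shares the direction of the length trend, 690 without CRE111 and 170 without NT1. Without CRE210 more genes were lower than higher (2402 and 1628). With the length trend removed the count was 436, with 211 higher and 225 lower, and the genes of at least 300 nt named here for Oct4_DE as rising or falling also passed then.

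CRE111 had the most called genes against the other 11 libraries (508), although at an unadjusted p under 0.05 it had fewer (2538) than CRE210 (3801) and Oct4_DE (3551). Genes of the integrated stress response, through which cells adjust translation and amino acid synthesis, were lower: Nupr1 was at 14.6 FPKM against 60.5 and 71.7 in the NT libraries, Ddit3 at 15.5 against 45.3 and 57.9, Chac1 at 3.22 against 12.9 and 14.5, and the serine synthesis enzyme Psat1 at 125 against 213 and 209. Of the 19 members tested, 10 fell and none rose (11 lower and 0 higher adjusted over the list alone), and the list median was -0.64 log2 units against the other libraries (camera adjusted p = 1.0e-05; adjusted p = 0.74 with an estimated correlation).

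Genes of formative and primed pluripotency, the states that follow the naive one, were higher in CRE111. Sox3 (6.97 FPKM against 3.42 and 4.24), Pou3f1 (4.58 against 3.17 and 2.70), Dusp6 (46.9 against 32.9 and 31.2) and Pim2 (13.4 against 9.0 and 8.28) rose, 4 of 16 members, with none lower (5 higher adjusted over the list alone). The list median was 0.47 above the other libraries (camera adjusted p = 6.4e-06; adjusted p = 0.74 with an estimated correlation) and 0.25 above NT. The list was also called higher in NT1 (median 0.20, adjusted p = 6.6e-05) and NT2 (median 0.14, adjusted p = 0.0035). Nodal and TGF-beta targets had a median of 0.39 and 2 of 16 members higher, Ctgf (41.0 FPKM against 14.7 and 16.2) and Nodal (110 against 58.4 and 62.2); Id2 and Id3 were at 35.0 and 79.4 FPKM without passing. Camera gave that list an adjusted p of 0.00044 (adjusted p = 0.58 with an estimated correlation), and 5 members were higher adjusted over the list alone.

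5 further lists were higher in CRE111 by camera, none with an estimated correlation (adjusted p = 0.74 for each). The p53 response list had 5 of 24 members higher, among them Perp (42.1 FPKM against 12.1 and 15.5), Plk2 (65.3 against 25.9 and 30.5), Pmaip1 (54.7 against 33.3 and 35.8) and Cd80 (7.44 against 3.19 and 4.61); 7 were higher and 3 lower adjusted over the list alone. The Myc and ribosome biogenesis list had 3 of 20, Mycn, Myc and Cad, and 3 adjusted over the list alone. Markers of the 2-cell-like state had 2 of 17, Usp17le and Usp17la, which belong to a multicopy gene family, and 3 adjusted over the list alone. The primitive endoderm list had 2 of 13, the laminin gene Lamb1 and Cited1, with 4 adjusted over the list alone, and did not pass with the length trend removed (adjusted p = 0.051). The chromatin repressor list had no member passing alone, by either adjustment, and Uhrf1 stood at 154 FPKM against 130 and 124.

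The largest falls in CRE111 were in transcripts of non-coding RNA genes and of 2 protein-coding genes. Rmrp, the RNA of RNase MRP, was at 1.41 FPKM against 49.4 and 40.9, Rn45s, the ribosomal RNA precursor, at 855 against 4633 and 4114, and Mir6236 at 1107 against 11590 and 8998. Lars2, a mitochondrial leucyl-tRNA synthetase, was at 65.3 FPKM against 344 and 299, and Nupr1 was the fifth. The largest rises were all in small RNA genes: AF357399, Mir7-1, Snora2b, Mir719 and Scarna8, of which Mir7-1, Snora2b and Scarna8 were listed at 0 in both NT libraries. In all 508 genes were called, 235 higher and 273 lower, and the size rule counted 57 and 30. The limma count was 1001 with the length trend removed, with 588 higher and 413 lower. It was 913 without CRE210, where Oct4_DE had more, and 1045 without Oct4_DE, where CRE210 had more.

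The other 8 targets had 1 to 3 called genes each, all of them snoRNA or microRNA genes under 300 nt, and the NT libraries had 1 and 2. They were Mir6992 and Mir1291 (CRE132), Snord83b (CRE77), Mir708 (CRE140), Mir692-1 (CRE135), Mir3470b (CRE18), Snord35a and Mir3473e (CRE4), and Snora68, Snord8 and Mir8097 (CRE210), higher, and Snora33 (CRE32) and Mir692-2 and Gm12238 (CRE18), lower. With genes under 300 nt left out, limma called 0 genes in each of these 8 libraries. At an unadjusted p under 0.05 there were 3801 genes in CRE210 and 18 to 116 in the other 7, against 39 and 36 in NT1 and NT2. CRE210 had 4101 called genes when Oct4_DE was left out and 233 when CRE111 was left out. With the 2 NT libraries alone as reference, a fit with 1 residual degree of freedom, limma called 4 genes in CRE140 and 3013 to 6130 in the other 9 targets. By the size rule CRE210 had 13 genes at least doubled and 57 at least halved, and the other 7 had 16 to 26 in total. Among genes of 300 nt or more, chosen after their values were seen, the larger differences from NT in CRE210 included Ndufa4l2 (21.6 FPKM against 5.48 and 4.69), higher, and Zbed6 (1.55 against 9.57 and 8.70) and Adnp (0.77 against 6.30 and 4.89), lower. Without any difference, a share of 0.05 of tested genes is expected at an unadjusted p under 0.05. The 7 targets here other than CRE210, and both NT libraries, stayed below that share. Their reference holds CRE111, Oct4_DE and CRE210, which can widen its spread. No setting that kept the other targets in the reference left out all of these libraries together. Few called genes therefore do not show that a target had no effect.

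Glycolysis and hypoxia genes were called as a list in 3 targets and in NT1, where the median was 0.17 log2 units above the other libraries (camera adjusted p = 0.0034) and all 18 members were above NT2. In CRE210 the list median was 0.39 log2 units above the other libraries (camera adjusted p = 0.0086), with Pgk1 at 130 FPKM against 89.2 and 70.8 and Tpi1 at 513 against 349 and 310. In CRE18 it was -0.30 (adjusted p = 2.7e-05), with Ldha at 621 FPKM against 1070 and 980, and in CRE135 -0.24 (adjusted p = 0.00061), with Ldha at 584. In these 3 targets no single member passed limma over all genes, and only CRE210 had members that were higher adjusted over the list alone. In CRE132 all 19 stress response members were above the mean of the other libraries (median 0.37, adjusted p = 4.0e-11), with Trib3 at 48.9 FPKM against 21.2 and 22.8, and heat shock genes were higher (median 0.13, adjusted p = 4.8e-05), with Dnajb1 at 69.7 against 51.4 and 55.3. In CRE32 the Myc and ribosome biogenesis list (median -0.17, adjusted p = 5.2e-07) and the formative and primed list (median -0.27, adjusted p = 6.4e-06) were lower, with Myc at 11.8 FPKM against 21.0 and 20.2 and Foxd3 at 8.67 against 16.6 and 15.9. None of these lists passed with an estimated correlation (adjusted p = 0.74 for the glycolysis and CRE32 lists, adjusted p = 0.72 for stress and adjusted p = 0.58 for heat shock in CRE132). No single member of the CRE132 and CRE32 lists passed limma, over all genes or adjusted over the list alone, and 10 of 14 heat shock members were above the other libraries in CRE132. Higher stress response genes were not particular to CRE132. Against NT the list median was 0.46 there, 0.42 in CRE32, 0.40 in CRE135, 0.32 in CRE18 and 0.31 in CRE77, and only CRE111 was below 0. Lower glycolysis and hypoxia genes were not particular to CRE18 and CRE135 either. Against NT the median of that list was -0.355 in CRE111, -0.316 in CRE18, -0.298 in CRE135 and -0.146 in Oct4_DE. It was above 0 in CRE32, CRE140, CRE4 and CRE210.

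Further list calls carried no member that passed alone, by either adjustment. Markers of the 2-cell-like state were lower in CRE140 (median -0.21, camera adjusted p = 5.2e-07) and in CRE4 (median -0.30, adjusted p = 1.0e-05), but also in NT1 (median -0.27, adjusted p = 0.00049). The Myc and ribosome biogenesis list was lower in CRE77 (median -0.11, adjusted p = 0.00061), and p53 response genes were higher in CRE18 (median 0.18, adjusted p = 0.0056), with Mdm2 at 74.9 FPKM against 48.8 and 55.1. Each had an adjusted p of 0.74 with an estimated correlation.

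Over the 10 targets 39 list tests passed. NT1 passed 9 lists, more than any target, and NT2 passed 4. These calls are not a background free of targeting, because the other 11 libraries then hold all 10 targets. A shift shared by the targets would appear in NT with the opposite sign. The 7 lists that passed the pooled comparison, described below, were all among those of NT1, with the opposite sign. This overlap is no separate support for a shared shift. NT1 itself belongs to the NT group of the pooled comparison and is set against the same targets in both fits. Between NT1 and NT2, where no target enters, 9 of 22 lists fell outside the central range of random lists. In NT1 the lists of cholesterol synthesis, core and naive pluripotency, formative and primed pluripotency, glycolysis, interferon response and Myc were higher, and those of the 2-cell-like state, stress response and p53 response lower. In NT2 the cholesterol synthesis, formative and primed, Myc and 2-cell-like lists were higher. Cholesterol synthesis genes, for example, were higher in NT1 (median 0.16, adjusted p = 7.7e-06) and NT2 (median 0.11, adjusted p = 0.0056). No list passed in any library with an estimated correlation, where the smallest adjusted p was 0.33, for trophectoderm in Oct4_DE.

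**Figure D3:**
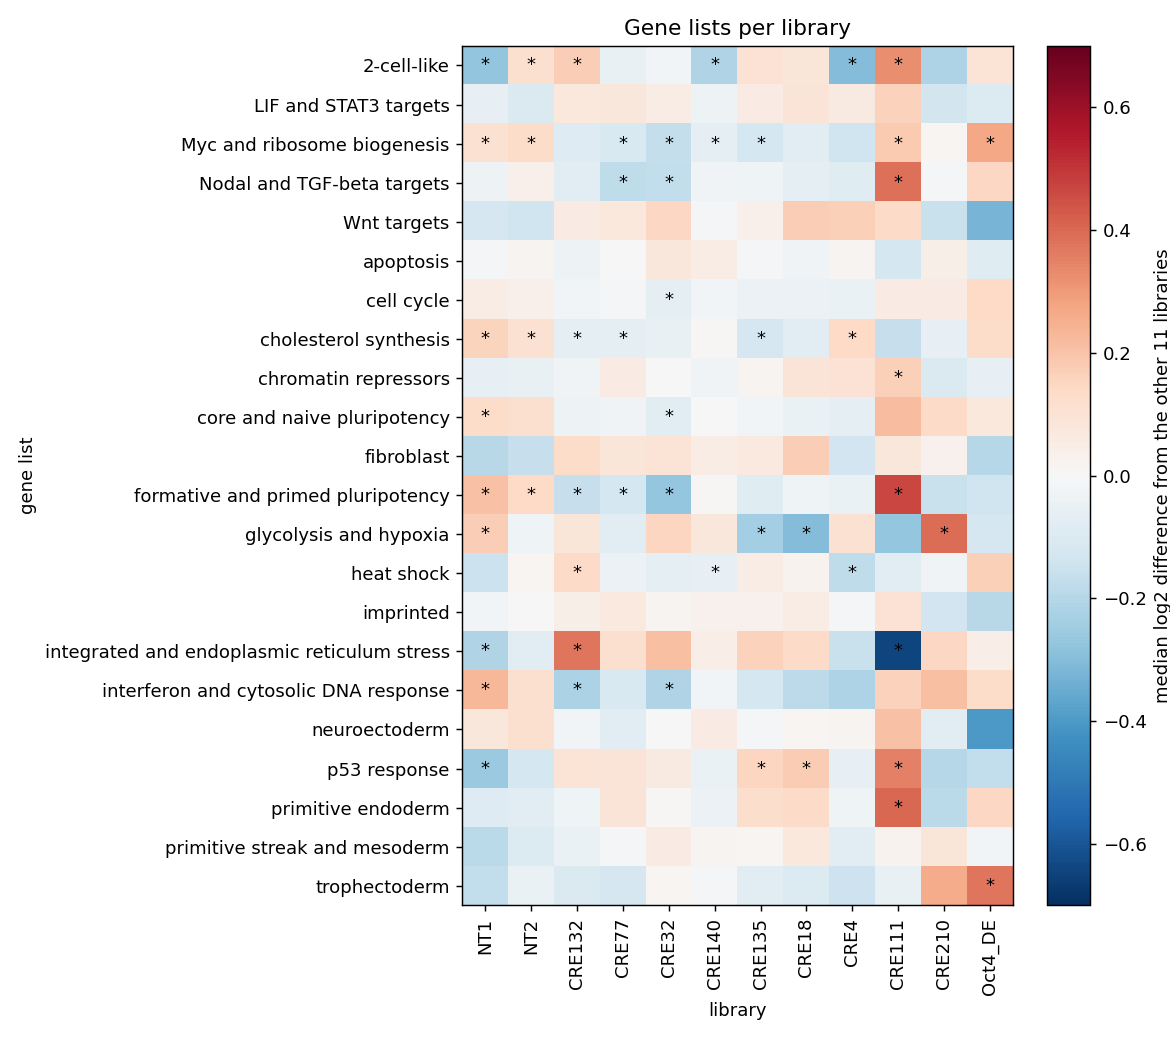
Median log2 difference of each gene list in each library from the other 11 libraries (colour), with a star where camera with the preset correlation gave an adjusted p under 0.05. NT1 has 9 stars, CRE111 has 8 and Oct4_DE has 2.

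The pooled comparison asks what the 10 different targets share against NT. No gene passed limma (461 of 11642 at an unadjusted p under 0.05), and the smallest adjusted p was 0.945. Without any difference, a share of 0.05 of tested genes would be expected at that unadjusted p, and 461 lies below it. As lists, cholesterol synthesis, formative and primed pluripotency, Myc and ribosome biogenesis, core and naive pluripotency and interferon response genes were lower in the targets, and p53 response and stress response genes were higher. For cholesterol synthesis, 16 of 18 members were below NT (median -0.15, camera adjusted p = 3.3e-05). For p53 response, 22 of 24 were above (median 0.22, adjusted p = 0.00046). Adjusted over the list alone, 2 formative and primed members were lower and 1 stress response member higher, and no member of the other 5 lists passed. Values behind them were 2.89 ± 0.75 FPKM in the targets (SD, n = 10) against 5.40 ± 0.45 in NT (SD, n = 2) for Fgf15, 15.7 ± 1.27 against 19.7 ± 0.89 for Otx2, 60.9 ± 4.65 against 49.1 ± 0.79 for the cell cycle inhibitor Cdkn1a, 77.4 ± 11.5 against 52.4 ± 4.52 for Ddit4, and 15.4 ± 1.93 against 20.6 ± 1.67 for the sterol enzyme Nsdhl. With an estimated correlation no list passed (adjusted p of at least 0.423). The other 15 lists did not pass with the preset correlation either. Once the length trend was removed, core and naive pluripotency (adjusted p = 0.052) and interferon response (adjusted p = 0.14) no longer passed, and neuroectoderm did (median -0.11, adjusted p = 0.043). Without NT1, 4 lists passed with the preset correlation in place of 7. The 2 NT libraries alone set the reference, so a library effect in them cannot be separated from an effect of targeting.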

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

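The tests in this part on transcript length, Pou5f1, depth, coding share and splits were chosen after the results were seen. Over the 10 enhancer-targeted libraries, 55 reported values were examined for a library whose gap to its nearest neighbour was larger, as a share of the whole range, than Dixon's critical value, and 21 had one. Chance alone gives about 1 in 20, but most of these values are genes named because 1 library stood apart, so the number carries no weight of its own.

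Pou5f1 was highest in CRE210, at 958 FPKM, with the next library at 774. In CRE111, Lars2 (65.3 FPKM, next 271), Rn45s (855, next 2987) and Rmrp (1.41, next 21.4) were low, the median of the formative and primed list against NT was high (0.25, next -0.16) and that of the stress response list was low (-0.55, next 0.01). In Oct4_DE the high values were Khdc3 (86.4 FPKM), Trim43a (15.8), Ly6a (33.9), Tagln (6.18), Calcoco2 (134), Crxos (28.6), Alppl2 (12.2), Sfn (52.96), Gm9112 (5.49) and the cell cycle list median (0.097). That median was high beside the other targets only: it stood at percentile 27.71 of random lists matched on level in Oct4_DE. The low values in Oct4_DE were Fstl1 (4.68 FPKM), Mcf2 (3.45), Napsa (1.49), Atp2a3 (3.42) and Sfrp1 (8.05).

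The genes that set Oct4_DE apart were weighed against the length trend. Once that trend was removed, 79.9% of the called genes of at least 300 nt were still called in the same direction, which argues against length as the whole cause. A lower Pou5f1 level, the effect that the target names, stays open: Pou5f1 did not pass in the deposited values (adjusted p = 0.4696) and passed with the length trend removed (adjusted p = 0.027), and 1 library cannot show which is right. Clonal or library differences unrelated to the guide were not tested and stay open too.

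The genes that set CRE111 apart were weighed in the same way. With the length trend removed, 84.6% of the called genes of at least 300 nt were still called in the same direction. Low depth was tested on the 4 libraries with fewer estimated reads than CRE111, and 0 genes of at least 300 nt were called in them. A lower yield of ribosomal and other non-coding RNA could account for Rn45s and Rmrp. It could reach a protein-coding gene if ribosomal reads are assigned to that gene, as considered below for Lars2. Protein-coding genes made up 89.7% of the called genes that fell. The coding share of all tested genes was not taken, so this share cannot be weighed as a test of that explanation. An effect of the targeted element cannot be separated from any other property of this single library.

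The pooled comparison was set against all splits of the 12 libraries into 10 and 2. The real split gave 461 genes at an unadjusted p under 0.05, and 19 of 66 splits, itself included, gave as many, so chance is not excluded. Each of the others among them set CRE111, CRE210 or Oct4_DE apart. Of the splits that set none of these libraries apart, the real one was highest, followed by CRE32 with CRE4 at 456. Both counts lie below the share of 0.05 of tested genes expected without any difference. With the length trend removed these 2 splits gave 886 and 515, the first above that share and the second below it. The highest other split, CRE210 with Oct4_DE against the rest, gave 6438, with 5660 passing adjustment and 2846 after removal of the length trend, which points to a structure of the samples. CRE111 with Oct4_DE came next, with 2924 genes, 865 passing adjustment and 1873 after removal of the length trend, so the structure is not one of CRE210 with Oct4_DE alone.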

How the results depend on the processing

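The alternatives named here as leaving out genes under 300 nt, removing trends, or leaving out CRE210, Oct4_DE or CRE111 were chosen after seeing the data. No paired analysis was possible because each target has 1 library and the numbers of NT1 and NT2 pair with none of them. Depth is known only as rough relative reads, so it sets no limit that can be given here. For each moved result the cause was not tested, except where the sentence names it. Leaving out genes under 300 nt has no effect on the Pou5f1 level and was not run for it.

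Without a filter on level, which adds low genes, 23 genes were set apart in CRE132, 32 in CRE77, 29 in CRE32, 70 in CRE140, 112 in CRE135, 48 in CRE18, 24 in CRE4, 1163 in CRE111, 37 in CRE210 and 433 in Oct4_DE. A mean of at least 5 FPKM, which tests fewer genes, left 0 in CRE132, 1 in CRE4, 335 in CRE111 and 130 in Oct4_DE. Leaving out genes under 300 nt, removing the length trend, or removing length and GC trends each left 0 in the 8 targets other than CRE111 and Oct4_DE, because their calls were such genes. Length removal gave 1001 in CRE111 (588 higher, against 235 of 508) and 436 in Oct4_DE (211 higher, against 156 of 267), and length and GC removal gave 1136 in CRE111. With the 2 NT libraries alone as reference, on 1 residual degree of freedom and assuming that the target varies like NT, the counts were 3013 in CRE132, 3937 in CRE77, 5361 in CRE32, 4 in CRE140, 4411 in CRE135, 4755 in CRE18, 5046 in CRE4, 5861 in CRE111, 6130 in CRE210 and 5805 in Oct4_DE. Without NT1, NT2, CRE210, Oct4_DE or CRE111, the only libraries left out in turn here, counts were 2 in CRE132, 1 in CRE32, CRE140 and CRE135 and 3 in CRE18 each time, and ran from 1 to 2 in CRE77, 2 to 3 in CRE4, 412 to 1045 in CRE111, 3 to 4101 in CRE210 and 170 to 4030 in Oct4_DE. With the length trend removed as well, leaving out CRE210 gave 1265 in CRE111 and 2119 in Oct4_DE, leaving out Oct4_DE gave 1920 in CRE111 and 1251 in CRE210, leaving out CRE111 gave 1 in CRE18, 53 in CRE210 and 1457 in Oct4_DE, and each gave 0 in the other targets.

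By the size rule, a pseudocount of 0.1 gave 36 genes in CRE132, 33 in CRE77, 72 in CRE32, 38 in CRE135, 35 in CRE18, 40 in CRE4, 194 in CRE111, 154 in CRE210 and 182 in Oct4_DE, and a mean of at least 5 FPKM gave 11 in CRE132 and 53 in Oct4_DE. Without genes under 300 nt there were 7 in CRE132, 4 in CRE77, 3 in CRE140, 12 in CRE135, 4 in CRE18 and 7 in CRE4. Length removal gave 9 in CRE132, 6 in CRE77, 4 in CRE140, 11 in CRE135, 5 in CRE18, 4 in CRE4, 26 in CRE210 and 49 in Oct4_DE. Length and GC removal gave 7 in CRE132, 4 in CRE77, 16 in CRE32, 4 in CRE140, 10 in CRE135, 4 in CRE18, 4 in CRE4, 24 in CRE210 and 52 in Oct4_DE. With 1 NT library as reference the ranges were 32 to 35 in CRE132, 33 to 36 in CRE77, 48 to 50 in CRE32, 29 to 30 in CRE140, 46 to 49 in CRE135, 36 to 37 in CRE18, 36 to 42 in CRE4, 119 to 145 in CRE111, 95 to 104 in CRE210 and 108 to 119 in Oct4_DE, as a rule on 1 library is easier to meet.

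The pooled comparison gave 3 genes without a filter (Gm15850, Gm35584 and Spag11a) and 0 to 2 when 1 library was left out: Mir615 and Snord33 without NT1, Snora36b without NT2 and Mir8112 without CRE32, all small RNA genes. With an estimated correlation 0 lists passed, pooled or per target, with or without the length trend. When 1 of the same 5 libraries was left out, pooled list counts ran from 4 to 9 and per-target list counts from 33 to 43, and random lists gave 85 per-target medians outside the middle range. Of the 39 per-target calls, 27 held under every camera setting run except an estimated correlation. By random lists, which use the difference from NT, 8 of the 39 lay inside the central range, among them core and naive pluripotency in CRE32, heat shock in CRE4, and Myc and ribosome biogenesis in Oct4_DE and CRE77. Cholesterol synthesis in CRE4 was higher than in the other libraries but had a median of -0.048 against NT.

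For Pou5f1, centring moved the log2 difference from NT to -0.32 in CRE132, -0.34 in CRE77, -0.45 in CRE32, -0.21 in CRE140, -0.35 in CRE18, 0.16 in CRE210 and -0.43 in Oct4_DE. Length removal gave -0.18 in CRE132 and CRE77, -0.29 in CRE32, -0.11 in CRE140, -0.17 in CRE135, -0.15 in CRE18, -0.13 in CRE4, 0.13 in CRE111, -0.10 in CRE210 and -0.63 in Oct4_DE. Length and GC removal gave -0.26 in CRE132, -0.29 in CRE77, -0.38 in CRE32, -0.14 in CRE140, -0.25 in CRE135, -0.26 in CRE18, -0.19 in CRE4, 0.092 in CRE111, -0.21 in CRE210 and -0.75 in Oct4_DE. The sign in CRE111 and CRE210 turned under both removals.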

Other observations

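Tests in this part on Hedgehog targets, on Lars2 and on neighbouring genes were set down before their results were seen. The genes of the next 2 paragraphs were chosen after their values were seen.

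Some transcripts of the Hedgehog pathway, which patterns the embryo, were higher in CRE111. Ptch1 stood at 18.0 FPKM against 5.55 ± 0.38 in NT (SD, n = 2), the transcription factor Gli1 at 19.2 against 9.62 ± 0.041, and Nkx2-9 at 17.6 against 3.90 ± 0.23, each with a limma adjusted p of 0.022 or lower. As a hypothesis, the pathway may be more active in this library. Of 10 other tested Hedgehog target or pathway genes, 8 were above NT, with a median of 0.31 log2 units at the 99.55th percentile of 10000 random lists matched on level. That is weak evidence: CRE18 and CRE135 stood at percentiles 98.39 and 98 on the same genes, and 9 of 22 lists fell outside the central range of their random lists between NT1 and NT2. With the length trend removed CRE111 was at percentile 99.45 and CRE18 at 99.36. Mycn was the only one of the 10 to pass limma alone in CRE111 (adjusted p = 0.0022), and Rab34 and Smo were below NT (-0.40 and -0.20 log2 units).

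The list of imprinted genes did not pass in CRE111 (median 0.10, camera adjusted p = 0.41), with 2 of 20 members higher and 1 lower. Peg10 was at 130 FPKM against 45.5 ± 1.22 in NT (SD, n = 2) and Cdkn1c at 17.7 against 8.49 ± 0.014, both higher, and the non-coding Meg3 at 2.15 against 4.46 ± 0.052, lower. Neat1, a nuclear non-coding RNA, was at 31.9 FPKM against 84.7 ± 1.13 and passed limma (adjusted p = 0.025), and it was also low in Oct4_DE, at 50.1 FPKM. Malat1 was at 60.2 against 116 ± 1.36 and did not pass (adjusted p = 0.33), and it was lower still in Oct4_DE (51.8 FPKM) and CRE210 (55.1). In Oct4_DE, Dppa3 (11.6 FPKM against 3.85 ± 0.013), Pramel7 (17.3 against 5.59 ± 1.14) and Pramel6 (11.97 against 5.57 ± 1.19) rose. The lists that hold them went different ways: against NT the core and naive pluripotency list had a median of -0.042, at percentile 0.18 of random lists, and the 2-cell-like list one of 0.16, at percentile 98.58 (92.24 with the length trend removed). Neither passed camera in Oct4_DE (adjusted p = 0.51 and 0.062).

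Lars2 and Mir6236 fell together with Rn45s in CRE111. A candidate explanation is that reads of ribosomal RNA are assigned to these genes. Over the other 11 libraries, log2 Lars2 and log2 Rn45s had a Pearson r of 0.511 (permutation p = 0.11) and a Spearman rho of 0.491 (permutation p = 0.13), and r was 0.141 without NT1 and Oct4_DE, the 2 libraries farthest from the median, so the data do not decide for Lars2. For Mir6236 r was 0.881 (permutation p = 0.00045, adjusted over both relations 9e-04) and rho 0.809 (permutation p = 0.00407), and r was 0.673 without those libraries.

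If a targeted element acted on several neighbouring genes, these could fall together. The guide positions are not used here, so the 50 falling genes with the smallest p in each library were searched for pairs within 5 gene places of each other. Each library had 0 or 1 such pairs, against a mean of 0.37 in 10000 random sets, and the smallest adjusted p over the 12 libraries was 0.4674. A fall of a single neighbouring gene would not show in this test. A joint fall of 1 pair of neighbours would not pass on its own either, because random sets held 0.37 pairs on average. The result therefore does not speak against an effect on so few neighbouring genes.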
